A study of Mus musculus with 12 samples.

How the data were processed

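RNA was measured in 12 libraries of mouse peritoneal macrophages, the resident phagocytes of the abdominal cavity, from wild-type (WT) mice and from mice lacking Pim1 (Pim1-/-). Cells of each genotype were treated with PBS or with 20 µg/mL oxidized low-density lipoprotein (oxLDL) for 8 h, which gives 4 groups of 3 libraries. Per the labels' protocols, total RNA was purified on columns and checked on a Bioanalyzer, and stranded poly(A) mRNA libraries were sequenced on a HiSeq 2500. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, so every p-value measures the spread between these samples, which can be technical.

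The values used here are TPM, a transcript abundance corrected for length and scaled to a fixed total per library, for each gene in 1 table of 24279 genes, deposited by the authors, and every library sums to the same total. The submitters' processing notes name Salmon, a tool that estimates transcript levels from reads, DESeq2 and the mm10 mouse genome build, without versions. The role of DESeq2 and the gene annotation behind the table were not given in the sources used here. TPM keeps no sequencing depth, so the depth of each library is unknown, no counting interval can be given, and no count model was used. Of the 24277 distinct names, 98.2% matched a gene of GENCODE release M21, which was used for gene length, GC content and position. In 27 rows the name had turned into a date, and these rows were kept under that name.

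Values were analysed as log2(TPM + 1), so the changes of genes with low TPM are understated. Genes at a TPM of at least 1 in at least 3 libraries were tested, which left 12594. A model of the 4 group means over all 12 libraries, with 8 residual degrees of freedom, was fitted with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with an intensity trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were the knockout in PBS, the knockout in oxLDL, oxLDL in WT, oxLDL in Pim1-/-, the difference of the oxLDL responses between genotypes, and the knockout averaged over treatments. Changes are given with the standard error (SE) of the model, and group means with the standard deviation (SD) over 3 libraries. Pim1 itself was also compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.1.

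Gene lists were fixed before the data were examined, as were the contrasts, the tests and the rule for naming genes. Of their 610 members 20 were not found in the table. The 28 lists of biology or cell types with at least 3 tested members were tested per contrast with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. The Pim kinases and the lists of immediate early and heat shock genes and of histone genes were left out of these tests. The camera test compares a list with all other tested genes, so it is relative to the shift of those genes. Members were also adjusted over the list alone. Named genes are the Pim kinases, up to 10 called genes per direction with the largest change, groups that do not overlap and a mean TPM of at least 5, and up to 2 called members per list and direction. Where no member passed, the 2 members with the smallest p are eligible, and where fewer than 10 genes passed, the 10 genes with the smallest p. Genes named outside this rule are said to be so, and some genes that meet it are not reported here.

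The processing choices tried in turn were other pseudocounts, other filters on low values, scaling of the libraries by the median ratio to the mean library (called median scaling below), quantile normalization, rescaling without ribosomal protein genes, a minimum change of 1, no intensity trend, a fit of the compared groups only, a replicate block and leaving out each library. Those added after the data had been seen were leaving out Rn45s and Mir6236, rows that hold ribosomal RNA sequence, removing a trend with gene length and GC content from each library, and leaving out a pair of closely similar libraries. The trend was removed as medians over 20 bins, and the outermost bins were divided further at 1%, 2% and 3% after a test on simulated data showed that undivided ones left part of the trend among short RNAs. Removing it also took the median deviation off each library, so this alternative takes off the shift of a library as well. In that simulation the largest slope on length went from 0.609 to 0.00354 over 12594 genes.

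The fit and the calls were tested on simulated log2 values with known changes in some of 12594 genes. Each gene had independent normal noise, without the fixed TPM total, the filter or differences shared across a library. The shares below are therefore not the error rates of these data. For the knockout in PBS it recovered 1.49%, 40.3% and 93.9% of genes with a true log2 change of 1, 2 and 4. For the knockout in oxLDL these shares were 5.97%, 46.3% and 87.9%, and for the difference of oxLDL responses 1.49%, 7.46% and 72.7%. Unchanged genes called by mistake numbered 4, 4 and 3. Genes that share sequence with close relatives, such as Ly6c2 and Ly6i, Bcl2a1a and Bcl2a1d, Saa3, Gbp5 and the class II genes, have uncertain values, since the assignment of shared reads is not described.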

Results

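The series measured gene expression in peritoneal macrophages of WT and Pim1-/- mice after PBS or oxLDL, with 3 libraries in each of the 4 groups. Pim1 is a serine/threonine kinase whose gene is induced by cytokine signalling through JAK and STAT proteins. OxLDL is a modified lipoprotein that macrophages take up through scavenger receptors, and it is widely used to load these cells with lipid. The comparisons ask how macrophages respond to oxLDL, how the loss of Pim1 alters untreated and treated cells, and whether the response differs between genotypes. All levels are TPM and sequencing depth is unknown.

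Pim1, on chromosome 17 (29490753 to 29496112, GRCm38/mm10, GENCODE M21), was lower in every knockout library than in every WT library. It stood at 93.1, 68.5 and 77.6 TPM in the WT PBS libraries and at 365, 56.0 and 114 TPM in the WT oxLDL libraries. The Pim1-/- libraries held 13.9, 10.2 and 30.6 TPM in PBS and 47.8, 13.6 and 12.3 TPM in oxLDL, so reads assigned to the gene remained. The labels do not say which part of the gene was removed, and a value per gene does not show where its reads lie. The log2 difference between genotypes was -2.20 (SE 0.652) in PBS and -2.67 (SE 0.652) in oxLDL, with an exact permutation p of 0.1 in each, the smallest that 3 against 3 libraries allow. Among all tested genes neither passed (limma adjusted p = 0.0662 and 0.321), and median scaling gave -1.59 in PBS. The related kinase Pim2 differed by -1.41 in PBS and -0.79 in oxLDL, with an exact permutation p of 0.1 each, and Pim3 by -0.22 and -1.42 (exact permutation p = 0.9 and 0.3). OxLDL changed Pim1 by 0.74 in WT and 0.28 in Pim1-/- cells, neither past the test (limma adjusted p = 0.399 and 0.805).

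**Figure D1:**
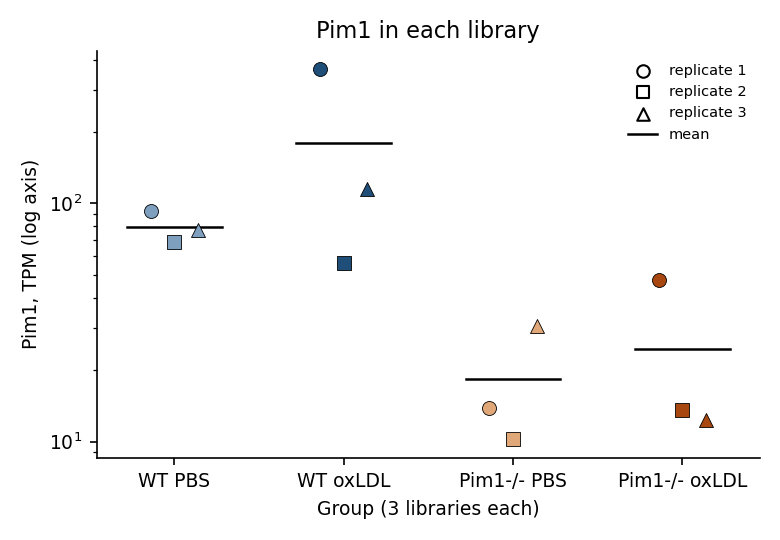
Pim1 in TPM (log axis) in each of the 12 libraries by group, with the mean of each group as a line and the replicate as the marker shape. The knockout libraries lie between 10.2 and 47.8 TPM and the WT libraries between 56.0 and 365 TPM.

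The libraries separated by treatment along a first principal component that held 50.3% of the variance. It also parted the genotypes in PBS, with WT at -110, -119 and -90.7 and Pim1-/- at -18.6, -66.6 and -2.44. The values were unscaled, and the median ratio to the mean library was 1.81 at its low end (WT PBS 2) and 0.665 at its high end (Pim1-/- oxLDL 3, at 92.7). That share of the variance is therefore not a measure of treatment alone. WT PBS 3 stood apart from the other PBS libraries, with a highest Spearman correlation of 0.837 with any library and 12867 genes listed at 0. It held the lymphocyte transcripts Nkg7 at 333 TPM and Cd3d at 61.5 TPM, while WT PBS 1 and 2 held 0.508 and 1.79 TPM of Nkg7. WT oxLDL 2 correlated most closely with a library of the other genotype, Pim1-/- oxLDL 1 (0.977). It was also closer to the other Pim1-/- oxLDL libraries (0.94 and 0.947) than to the other WT oxLDL libraries (0.884 to 0.899). Pim1-/- PBS 2 was likewise closest to a WT library, WT PBS 1 (0.916). The ribosomal RNA row Rn45s took 3.01% to 28.9% of TPM and Mir6236 took 0.0312% to 25.8%. Since TPM sums to a fixed total, such shares move all other genes. Together they were 13.5%, 19.5% and 11.7% in WT PBS and 32.7%, 21.2% and 15% in WT oxLDL. In Pim1-/- cells they were 25.7%, 14.9% and 29.4% in PBS and 21.7%, 14.8% and 17.1% in oxLDL. These shares thus do not account for the median fall with oxLDL in Pim1-/- cells given below. Rescaling without both rows still left 817 rises and 3052 falls for oxLDL in WT. The median ratio of a library to the mean library averaged 1.69 in WT PBS, 0.844 in WT oxLDL, 1.13 in Pim1-/- PBS and 0.701 in Pim1-/- oxLDL. Accordingly the median log2 change of all tested genes was -0.41 for the knockout in PBS, -0.17 for the knockout in oxLDL, -0.70 for oxLDL in WT and -0.50 for oxLDL in Pim1-/- cells. List medians called relative have this shift taken off.

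**Figure D2:**
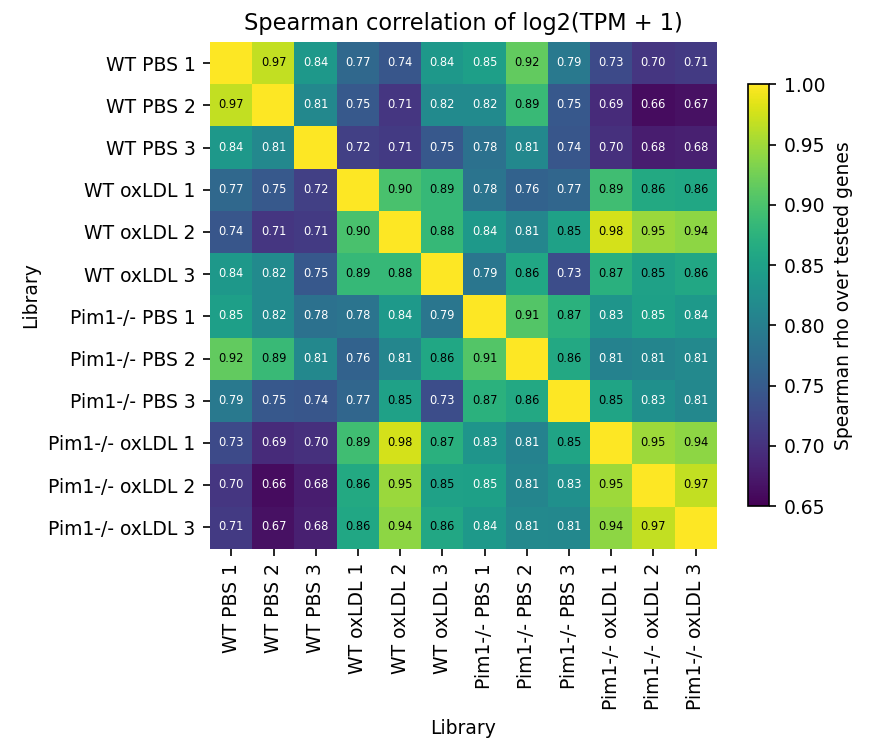
Spearman correlation of log2(TPM + 1) between each pair of the 12 libraries (both axes) over the tested genes, with the colour scale and the printed value giving rho. WT oxLDL 2 and Pim1-/- oxLDL 1 correlate at 0.977, and WT PBS 3 reaches at most 0.837.

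In WT macrophages oxLDL raised inflammatory and interferon-induced genes, several of them from a mean under 1 TPM. Il1b, which encodes the cytokine interleukin-1 beta, went from 0.175 ± 0.303 to 3210 ± 942 TPM (SD, n = 3), a log2 change of 11.40 (SE 0.381). The chemokine gene Cxcl10 went from 0.587 ± 1.02 to 2170 ± 437 TPM, and Nos2, the inducible nitric oxide synthase, from 0.0467 ± 0.0407 to 521 ± 152 TPM. All 30 tested members of the list of NF-kB targets and inflammatory cytokines rose, and 31 of the 32 interferon response genes rose, with the same counts adjusted over the list alone. Their median changes were 5.99 and 5.25 (relative 6.70 and 5.96). Both lists were called by camera (adjusted p = 3.72e-57 and 5.04e-53), with adjusted p = 6.76e-06 and 0.00462 with an estimated correlation. Gbp5, an interferon-induced GTPase, rose by 9.83, and Irg1, which makes itaconate, by 8.48.

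Genes of cholesterol synthesis fell in WT cells treated with oxLDL. Of the 25 SREBP2 targets 20 fell and none rose, with 20 also adjusted over the list alone, and the median change was -2.31 (relative -1.61). Dhcr7 and Sqle, enzymes of the pathway, changed by -3.96 (SE 0.455) and -3.96 (SE 0.437), Sqle from 134 ± 28.1 to 7.89 ± 2.96 TPM (SD, n = 3). The list passed (adjusted p = 1.9e-05), but not with an estimated correlation (adjusted p = 0.253 with an estimated correlation), and after median scaling 12 members fell. LXR targets, which respond to sterols, moved both ways. Mylip (2.42) and Nr1h3 (1.67) rose, 3 members including Acsl3 (-2.64) and Scd2 (-2.59) fell, 8 of 13 did not pass, and the list was not called (adjusted p = 0.841). Among 22 PPAR targets and lipid droplet genes 2 rose and 10 fell, while median scaling gave 3 rises and 3 falls (adjusted p of the list = 0.161). Pparg, the lipid-activated nuclear receptor, changed by -4.30 (SE 0.456), and Soat1, which esterifies cholesterol, by -3.29 (SE 0.494). Of 15 scavenger and lipoprotein receptors 4 rose and 6 fell, 4 and 5 after median scaling, and the list was not called (adjusted p = 0.517). Marco (3.87) and the oxLDL receptor Olr1 (2.49) rose, and Clec7a (-3.16) and Lrp1 (-2.35) fell.

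Further lists were called in WT cells. Among 17 JAK-STAT targets 8 rose and Bcl6 (-1.69) fell (adjusted p = 2.15e-07, and adjusted p = 0.107 with an estimated correlation), with the feedback inhibitors Socs1 at 6.91 and Socs3 at 6.15. Of 14 inflammasome genes 8 rose, among them Il18 (4.38), and Nlrp1b (-2.97) fell (adjusted p = 1.27e-06, and adjusted p = 0.142 with an estimated correlation). Markers of small peritoneal and monocyte-derived macrophages rose in 5 of 10 cases and fell in 2, Ccr2 (-1.83) and F13a1 (-1.74), and this list held with either correlation (adjusted p = 0.000108, and adjusted p = 0.0208 with an estimated correlation). Its member Ms4a4c rose by 8.17, and Ly6c2 was listed at 0 in all 3 WT PBS libraries and averaged 71.4 ± 41.6 TPM (SD, n = 3) after oxLDL. A change in cell types was not separated from a response of these genes in the same cells. The list of class II antigen presentation (3 of 10 rose, adjusted p = 0.00103, and adjusted p = 0.107 with an estimated correlation) included H2-Ab1 at 2.34 and Cd86 at 2.03. B cells also carry class II genes, and the B cell marker score (the median deviation of members from their means, relative to all genes) was -1.03, -1.13 and -1.25 in WT PBS and -0.155, 0.406 and -0.628 in WT oxLDL (list not called, adjusted p = 0.226), so the 2 were not separated. Glycolysis genes had 3 rises, including Pfkfb3 (2.52), and 1 fall among 23 (adjusted p = 0.000525, and adjusted p = 0.356 with an estimated correlation), and 15 rises after median scaling. Mitotic and replication genes fell in 9 of 25 cases, including Ccnb1 at -2.20, and in 2 cases after median scaling (adjusted p = 0.0483, and adjusted p = 0.56 with an estimated correlation). ATF4 targets (3 rose and 1 fell of 21, 9 and 0 after median scaling; adjusted p = 0.0302, and adjusted p = 0.356 with an estimated correlation) were led by Nupr1 (2.79). The neutrophil list (7 tested, adjusted p = 0.0161, and adjusted p = 0.141 with an estimated correlation) had Lcn2 (6.79), an antibacterial protein that macrophages also make, as its only called rise, while Mmp8 (-2.76) fell. The mast cell list of 3 tested genes (adjusted p = 0.0161, and adjusted p = 0.107 with an estimated correlation) had Hdc (4.40), the histamine-forming enzyme, as its only called member. Adjusted over the list alone, rises and falls numbered 8 and 1 for JAK-STAT targets, 8 and 4 for inflammasome genes, 5 and 3 for monocyte-derived markers, 3 and 0 for class II genes, 2 and 0 for glycolysis genes, 0 and 11 for mitotic genes, 2 and 1 for ATF4 targets, 1 and 1 for neutrophil markers and 1 and 0 for mast cell markers. After median scaling they were 12 and 0 for JAK-STAT targets, 9 and 1 for inflammasome genes, 6 and 1 for monocyte-derived markers, 5 and 0 for class II genes, 2 and 1 for neutrophil markers and 1 and 0 for mast cell markers. Median scaling ended the calls of the mitotic (adjusted p = 0.0576), neutrophil (0.132) and mast cell lists (0.0588), and with single libraries left out the mitotic list lost its call in 7 of 12 fits (highest adjusted p = 0.122), the ATF4 list in 4 (0.0639) and the neutrophil list in 1 (0.0503).

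In all, 734 genes rose and 3403 fell with oxLDL in WT cells, while 1652 rose and 941 fell after median scaling, 1255 and 1386 after quantile normalization, and 1660 and 1419 with the length and GC trend removed, an alternative chosen after seeing the data. The medians of the LXR, scavenger receptor, large peritoneal macrophage, alternative activation and NRF2 lists lay below 0 while their camera tests pointed up, relative to the other genes. In 42.7% of the tested genes (1001 up and 4372 down) the 3 oxLDL libraries lay apart from the 3 PBS libraries in unscaled TPM. For a single gene 10% is the share by chance. A shift of a whole library moves its genes together, so such a share can lie far from 10% without changes of single genes. The largest falls were those of Arhgap19 (-5.20), Cd300lb (-5.01, an activating receptor of myeloid cells), Xylt1 (-4.90) and Idh1 (-4.85). The total of 4137 went to 2591 without WT oxLDL 2 and to 2617 without WT oxLDL 1, and quantile normalization gave 2641.

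In Pim1-/- macrophages the same inflammatory and interferon lists rose with oxLDL. Il1b went from 1.09 ± 0.737 to 2250 ± 172 TPM (SD, n = 3), a log2 change of 10.12 (SE 0.381), and Cxcl2, a neutrophil-attracting chemokine, changed by 9.18 (SE 0.39). The cytokine genes Il27 and Il6 rose by 8.62 and 7.86. Of the NF-kB list 29 of 30 members rose (30 adjusted over the list alone) with a median of 5.09, and of the interferon list 31 of 32 rose (32 adjusted over the list alone) with a median of 4.90. Camera called both (adjusted p = 5.26e-72 each), with adjusted p = 2.74e-06 and 0.00159 with an estimated correlation. Cholesterol synthesis genes fell in 13 of 25 cases and rose in none (20 falls adjusted over the list alone, 7 after median scaling), with a median of -1.48 (relative -0.98). Dhcr7 changed by -2.97 (SE 0.455) and Sqle by -2.87 (SE 0.437), and the list passed (adjusted p = 1.38e-06) but not with an estimated correlation (adjusted p = 0.202 with an estimated correlation). Cd300lb (-4.54, SE 0.486) and Idh1 (-4.17, SE 0.532) were among the falls.

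The remaining lists called in Pim1-/- cells were mostly those called in WT cells. JAK-STAT targets had 6 rises, among them Socs3 (4.98), and 1 fall, Bcl6 (-1.64), among 17 (adjusted p = 1.92e-07, and adjusted p = 0.1 with an estimated correlation). Inflammasome genes had 8 rises and 1 fall among 14 (adjusted p = 5.21e-08, and adjusted p = 0.104 with an estimated correlation). Monocyte-derived macrophage markers rose in 5 of 10 cases, Ms4a4c by 7.07, and held with either correlation (adjusted p = 1.98e-06, and adjusted p = 0.00694 with an estimated correlation). Here too a change in cell types was not separated from a response of the same cells. Cd86 (3.00) was the only class II presentation gene of 10 to rise (adjusted p = 0.00138, and adjusted p = 0.104 with an estimated correlation), and the B cell marker scores went from -0.149, 0.0369 and 0.113 in PBS to 0.592, 0.993 and 0.867 in oxLDL (list not called, adjusted p = 0.0764). No member of the glycolysis list passed (adjusted p = 0.00134, and adjusted p = 0.332 with an estimated correlation), and 10 of its 23 members rose after median scaling. Lcn2 (5.66) and Camp (1.31) rose and Mmp8 (-2.23) fell among 7 neutrophil markers (adjusted p = 0.00369, and adjusted p = 0.1 with an estimated correlation). PPAR targets had 1 rise and 5 falls among 22, Pparg at -3.74 (adjusted p = 0.0442, and adjusted p = 0.462 with an estimated correlation). Apoptosis regulators had 5 rises and 4 falls among 22 (adjusted p = 0.035, and adjusted p = 0.222 with an estimated correlation), with the survival gene Bcl2a1d at 3.49 and the death-promoting genes Bcl2l11 and Bmf at -2.04 and -1.80. Adjusted over the list alone, rises and falls numbered 6 and 1 for JAK-STAT targets, 8 and 1 for inflammasome genes, 5 and 0 for monocyte-derived markers, 2 and 0 for class II genes, 0 and 0 for glycolysis genes, 3 and 1 for neutrophil markers, 1 and 10 for PPAR targets and 6 and 4 for apoptosis regulators. After median scaling they were 7 and 0 for JAK-STAT targets, 8 and 1 for inflammasome genes, 5 and 0 for monocyte-derived markers, 2 and 0 for class II genes, 3 and 0 for neutrophil markers, 1 and 3 for PPAR targets and 7 and 2 for apoptosis regulators. Median scaling ended the calls of the PPAR (adjusted p = 0.101) and apoptosis lists (0.065), and the PPAR list lost its call in 6 of the 12 fits that left out a library (highest adjusted p = 0.0959). The LXR list was not called (adjusted p = 0.824), and of its 13 members Scd2 (-2.86) fell. In all, 560 genes rose and 982 fell, against 967 and 507 after median scaling, 795 and 593 after quantile normalization, and 959 and 667 with the length and GC trend removed. Here 38.2% of the tested genes, 1075 up and 3733 down, separated the 3 oxLDL from the 3 PBS libraries in unscaled TPM (10% by chance for a single gene). The total of 1542 went to 688 without Pim1-/- oxLDL 3, 702 without Pim1-/- oxLDL 2 and 887 without Pim1-/- PBS 2.

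The responses of the genotypes were alike across genes. Over the 12594 tested genes, which are not independent replicates, their log2 changes correlated with Pearson's r = 0.834 and Spearman's rho = 0.737, and 77.5% moved the same way relative to the median shift. Of 734 and 560 rises 488 were shared, where independent lists would share 32.6, and of 3403 and 982 falls 887 were shared (265 for independent lists). Mir7678, a microRNA gene (chromosome 2, 164354313 to 164354383), was the only gene whose response differed between genotypes by limma (adjusted p = 0.0153), and 381 genes had an unadjusted p under 0.05. It was listed at 0 in the 9 libraries outside Pim1-/- oxLDL and at 10.4, 9.25 and 13.9 TPM there, and it lies over an exon of Slpi, a protease inhibitor gene, so that reads of the host transcript cannot be told from its own. Xylt1 (3.02) and Slco2b1 (2.76) followed without passing (adjusted p = 0.49 each). Leaving out WT PBS 3 gave 3 genes, leaving out WT PBS 2 or WT oxLDL 3 gave 2, and leaving out any of the other 9 libraries gave 0.

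Camera called 4 lists in the difference of responses, all toward a smaller rise or larger fall in Pim1-/- cells, and 0 members passed over all genes or adjusted over the list alone. The NF-kB list had a median difference of -0.46 (relative -0.69; adjusted p = 0.000185, and adjusted p = 0.0618 with an estimated correlation), with Il1b at -1.28 (SE 0.538). Its scores, relative to all genes, were -3.99, -3.87 and -3.37 in WT PBS and -2.36, -2.79 and -2.52 in Pim1-/- PBS, but 2.83, 3.12 and 3 in WT oxLDL and 3.1, 3.34 and 3.31 in Pim1-/- oxLDL. On these scores the smaller rise went with a higher start. The median change of its members with the knockout was 0.202 in PBS (relative 0.61) and -0.233 in oxLDL (relative -0.0683). The Il1b means given above were also lower in Pim1-/- oxLDL than in WT oxLDL, so a lower level after oxLDL is not excluded. Mesothelial and fibroblast markers had a median of -0.55 (adjusted p = 0.0109, and adjusted p = 0.72 with an estimated correlation). ATF4 and NRF2 targets had medians of -0.34 and -0.41 (adjusted p = 0.0453 each, and adjusted p = 0.776 each with an estimated correlation), with Chac1 at -1.06 and Hmox1 at -1.19. Beside these stands the fibroblast transcript Col1a1, named after its values were seen, at 336, 579.8 and 1230 TPM in Pim1-/- PBS and 154, 323 and 186 TPM in WT PBS. It is 1 member of a list of which 0 of 11 tested members passed for the knockout in PBS. Adjusted over the list alone, 0 rose and 1 fell there, and the list was not called (camera pointing up, adjusted p = 0.149). The 4 lists became 1 without WT PBS 1 or without WT oxLDL 3 and 2 without WT PBS 2. Of the 12 fits that left out a library the ATF4 list lost its call in 8 (highest adjusted p = 0.215), the NRF2 list in 7 (0.355) and the mesothelial list in 2 (0.11), and the NF-kB list kept it in all. None of the 4 was called between genotypes in oxLDL (adjusted p = 0.403 for NF-kB, 0.71 for mesothelial, 0.311 for ATF4 and 0.111 for NRF2).

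**Figure D3:**
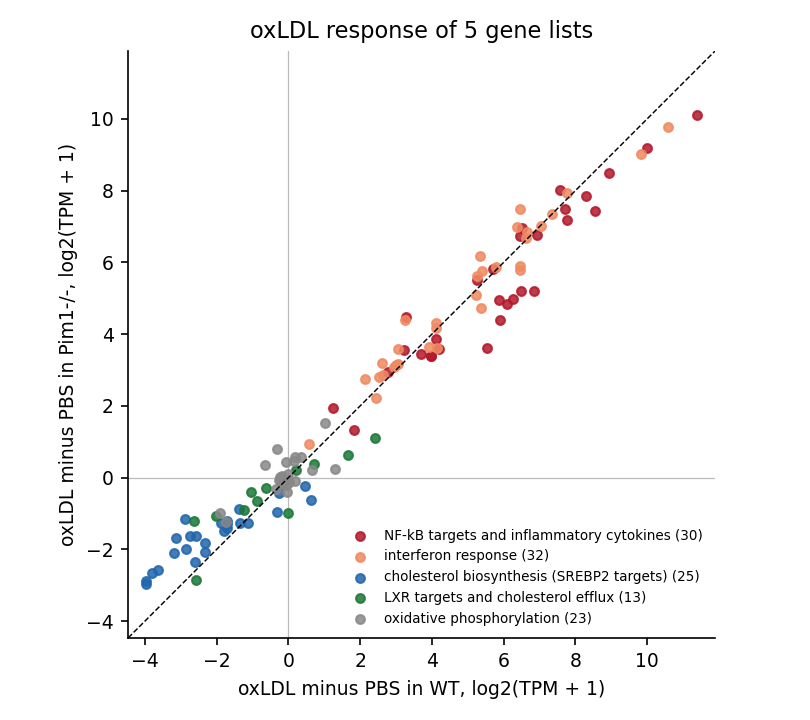
Log2(TPM + 1) change with oxLDL in WT (x axis) and in Pim1-/- macrophages (y axis) for the tested members of 5 gene lists, each point a gene and the dashed line marking equal change. NF-kB and interferon genes lie at the upper right (Il1b at 11.40 and 10.12) and cholesterol synthesis genes mostly at the lower left (Dhcr7 at -3.96 and -2.97).

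In untreated cells the knockout changed 588 genes, with 77 rises and 511 falls, a balance that scaling did not keep (2 and 3 after median scaling, 327 and 286 after quantile normalization). Lamp1, a protein of the lysosomal membrane, went from 3460 ± 307 TPM in WT to 205 ± 97.3 TPM in Pim1-/- cells (SD, n = 3), a log2 change of -4.20 (SE 0.599, limma adjusted p = 0.0115). Xylt1, which starts proteoglycan sugar chains, changed by -3.64 (SE 0.396, adjusted p = 0.00275), Uhmk1, a kinase, by -4.06 (SE 0.646), and Cebpa, a myeloid transcription factor, by -3.53 (SE 0.756). Orm1, an acute-phase protein, rose from 0.562 ± 0.773 to 32.9 ± 21.7 TPM (4.35, SE 0.866). Among the 10 largest named rises were also Mir7091, Mir7079, Mir6916 and Snord99, short RNA genes, of which Mir7091, Mir7079 and Mir6916 lie within other genes, Mir7079 over an exon of Rpl13, from which it cannot be told.

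Of 27 NRF2 targets 3 fell in untreated Pim1-/- cells and none rose (1 rise and 5 falls adjusted over the list alone). They included Gclc (-2.62, SE 0.519) and Gclm (-3.10, SE 0.775), the subunits of the enzyme that limits glutathione synthesis, and the list was not called (median -0.24, with the test pointing up relative to other genes; adjusted p = 0.712). Bcl2, a survival gene, changed by -1.69, the cholesterol transporter gene Npc1 by -1.77, Odc1 of polyamine synthesis by -2.39 and the integrin genes Itga6 and Itga4 by -2.23 and -1.83. After median scaling no member of any list passed. Class II genes H2-Eb1 (2.14, SE 0.492) and H2-Ab1 (2.03, SE 0.462) rose, 2 of 10 members (4 adjusted over the list alone), and the list was called (adjusted p = 0.00382, and adjusted p = 0.323 with an estimated correlation), though not without WT PBS 2 (adjusted p = 0.0654). The B cell marker scores given above were lower in each WT PBS library than in each Pim1-/- PBS library (list not called, adjusted p = 0.149). In the NF-kB list 3 of 30 members rose, among them Ccl7 (2.82, SE 0.689) and Saa3 (2.59, SE 0.651), and Nfkb1 (-1.62) fell, the same counts as adjusted over the list alone (adjusted p of the list = 0.000333, and adjusted p = 0.0897 with an estimated correlation). Scores of the monocyte-derived macrophage markers were -1.34, -1.47 and -1.21 in WT PBS and -0.268, -0.906 and -0.701 in Pim1-/- PBS (list not called, adjusted p = 0.149), so a change in cell types was not separated from this. Oxidative phosphorylation genes had a median of 0.79 (relative 1.2) with 0 of 23 members past the test over all genes or adjusted over the list alone (adjusted p of the list = 0.000152, and adjusted p = 0.407 with an estimated correlation). Beside this, ribosomal protein genes took 3.76 ± 2.72% of TPM in Pim1-/- PBS and 1.83 ± 1.2% in WT PBS (SD, n = 3), and the deviation of a gene from its mean correlated with its length at -0.0667 and 0.193 on average. Scores of replication-dependent histone genes, whose transcripts lack poly(A) tails, were 1.87, -0.78 and 1.49 in Pim1-/- PBS, where those of the oxidative phosphorylation genes were 0.756, -0.42 and 0.452, and -0.744, -0.972 and -0.373 in WT PBS. A difference in RNA quality or selection was thus not separated from the knockout. The ATF4 list (adjusted p = 0.0215, and adjusted p = 0.429 with an estimated correlation) had 1 rise among 21, Chac1 at 1.68 (2 adjusted over the list alone), and lost its call in 3 of the 12 fits that left out a library (highest adjusted p = 0.0953). Cholesterol synthesis and interferon genes had 0 members past the test over all genes or adjusted over the list alone (limma; adjusted p of the lists = 0.508 and 0.753).

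Of the 588 calls in untreated cells 346 were shared after quantile normalization, and 252 genes rose and 296 fell with the length and GC trend removed (310 shared). In 27.8% of the tested genes, 834 up and 2662 down, the groups did not overlap in unscaled TPM (10% by chance for a single gene). By limma 3546 genes had an unadjusted p under 0.05. With median scaling 5 genes were called, among them Xylt1, Slco2b1 (-2.83) and Rab40c (-2.61) as falls and Ppap2a (1.41) as a rise, of which Slco2b1, Rab40c and Ppap2a are named because of this count and not by the rule. The total of 588 went to 29 without WT PBS 1, 2 without WT PBS 2, 993 without WT PBS 3 (the library with lymphocyte transcripts), 99 without Pim1-/- PBS 1, 1669 without Pim1-/- PBS 2, 4 without Pim1-/- PBS 3, 355 without Pim1-/- oxLDL 1, 186 without Pim1-/- oxLDL 2 and 254 without Pim1-/- oxLDL 3, and the 4 lists became 2 without WT PBS 2. Of the 36 called genes eligible to be named in this comparison Xylt1 alone was called under every setting and with every library left out.

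In oxLDL-treated cells 1 gene, Mir7678, was called between genotypes by limma, and 1367 had an unadjusted p under 0.05. The genes next in order did not pass (adjusted p = 0.321 each) and included Gclm at -3.75 (SE 0.775), the kinase gene Uhmk1 at -3.16 (SE 0.646), Efhd2 at -2.47 (SE 0.486), Bcl3, an NF-kB cofactor, at -2.66 (SE 0.55), and Hamp, which encodes hepcidin, at 3.30 (SE 0.673). Lamp1 stood at 620 ± 618 TPM in WT and 101 ± 16.8 TPM in Pim1-/- cells (SD, n = 3; adjusted p = 0.36). Camera called 4 lists in which 0 members passed over all genes or adjusted over the list alone. Oxidative phosphorylation genes were higher as a list (median 0.71, relative 0.88; adjusted p = 1.4e-07, and adjusted p = 0.197 with an estimated correlation), with Cox6c at 2.11 and Cox5b at 1.90. Ribosomal protein genes took 4.07 ± 0.952% of TPM in Pim1-/- oxLDL and 1.48 ± 1.38% in WT oxLDL, and the deviation from the gene mean correlated with length at -0.213 and 0.0427 on average. Histone scores were 0.962, 1.2 and 0.788 in Pim1-/- oxLDL and -0.55, 0.768 and -1.9 in WT oxLDL, so RNA quality or selection was not separated from the knockout here either. Class II presentation genes (adjusted p = 0.00194, and adjusted p = 0.197 with an estimated correlation) had H2-Eb1 at 1.47. The 6 tested B cell markers were higher as a list (adjusted p = 0.00657, and adjusted p = 0.197 with an estimated correlation), Fcmr at 1.06, so the class II genes were not separated from the share of B cells. Adhesion and migration genes were lower as a list (23 members, median -0.59; adjusted p = 0.00588, and adjusted p = 0.814 with an estimated correlation), with Itgav at -2.02. This call was lost without WT oxLDL 3 (adjusted p = 0.113), whose list score of 0.919 stood above those of WT oxLDL 1 and 2 (0.19 and -0.242). In 19.9% of the tested genes, 866 up and 1635 down, the groups did not overlap in unscaled TPM (10% by chance for a single gene). The count of 1 became 317 without WT oxLDL 2, 11 without Pim1-/- oxLDL 1, and 2 without WT PBS 3 or without WT oxLDL 3. Without both WT oxLDL 2 and Pim1-/- oxLDL 1, an alternative chosen after seeing the data, it was 180. With the length and GC trend removed 1 gene, not Mir7678, was called, as a fall.

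Averaged over both treatments, the knockout changed Pim1 itself by -2.43 (SE 0.461, limma adjusted p = 0.00971), and among genes named above Lamp1 by -3.17 (SE 0.423) and Xylt1 by -2.13 (SE 0.28). Orm1 (3.56, SE 0.613) and H2-Ab1 (1.56, SE 0.326) rose. In all, 370 genes rose and 1034 fell, with a median shift of -0.30, while 798 rose and 454 fell after median scaling, 748 and 688 after quantile normalization, and 572 and 757 with the length and GC trend removed. The total of 1404 went to 901, 611 and 2534 without WT PBS 1, 2 and 3, to 639 and 619 without WT oxLDL 1 and 3, to 661, 2693 and 633 without Pim1-/- PBS 1, 2 and 3, and to 310 and 314 without Pim1-/- oxLDL 2 and 3. Within 10 Mb of Pim1, where a knockout can carry sequence of another strain, 14 of 343 tested genes were called in PBS (4.08%) against 569 of 12099 elsewhere (4.7%; odds ratio 0.862, two-sided Fisher's exact p = 0.698). The class II genes H2-Ab1 and H2-Eb1 and also Rab40c are among those 14 neighbours.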

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

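The list tests of the difference between the oxLDL responses of WT and Pim1-/- cells were chosen before the data were examined, and the comparison of Mir7678 with the gene it overlaps, the splits of the genotype labels given here and the added alternatives were chosen after the result was seen. The oxLDL response of Mir7678 differed between genotypes by 3.59 on the log2 scale, a value that rests on the pseudocount because the row is listed at 0 in 9 libraries. Its host Slpi rose with oxLDL in WT (3.77, limma adjusted p = 0.00218) and in Pim1-/- cells (3.10, adjusted p = 0.0144), and its own difference between genotypes was -0.68 (adjusted p = 0.986). That difference cannot decide whether Mir7678 holds reads of Slpi. Slpi was highest in the libraries where Mir7678 was seen, at 297.5, 315.6 and 358.2 TPM in Pim1-/- oxLDL. In WT oxLDL it stood at 107.4, 280 and 22.02 TPM. As lists, NF-kB targets and inflammatory cytokines (camera adjusted p = 0.000185), mesothelial and fibroblast markers (0.0109), ATF4 targets (0.0453) and NRF2 targets (0.0453) were lower in the response of Pim1-/- cells, though none was called between genotypes in oxLDL, and each lost its call with an estimated correlation (adjusted p = 0.0618, 0.72, 0.776 and 0.776).

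Chance is not excluded for the difference between genotypes as a count of genes. Among 100 splits of the genotype labels within treatment, with the additive effects of genotype and treatment taken out of each gene, 30 gave at least the 1 gene of the real split, the real one included. The highest other split called 319 genes by exchanging WT PBS 3 and WT oxLDL 3 with Pim1-/- PBS 2 and Pim1-/- oxLDL 1, and such a count can come from a structure of the samples, which was not tested. The splits first planned, of all 12 libraries, mix the treatments and decide nothing (22 of 100, highest other 4273).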

How the results depend on the processing

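Leaving out Rn45s and Mir6236, removing the length and GC trend and leaving out the close pair (WT oxLDL 2 and Pim1-/- oxLDL 1) were tests chosen after the data were seen. No called gene that is named and no called list changed direction under any alternative, while some lists without a call did, and the balance of rises and falls turned over with median scaling, from 734 and 3403 to 1652 and 941 for oxLDL in WT, from 560 and 982 to 967 and 507 in Pim1-/- cells and from 370 and 1034 to 798 and 454 for the averaged knockout, and quantile normalization took the knockout in PBS from 77 and 511 to 327 and 286. Of the named called genes 1 of 36 for the knockout in PBS, 63 of 88 for oxLDL in WT and 42 of 66 for oxLDL in Pim1-/- cells were called under every one, and Mir7678 was not in either contrast that called it. Among single genes, calls were lost in 349 and gained in 62 gene-by-setting cases for the knockout in PBS, 141 and 11 for oxLDL in WT, and 184 and 21 for oxLDL in Pim1-/- cells. The 588 genes of the knockout in PBS became 198 and 963 with pseudocounts of 0.1 and 5, 151 without a filter, 5 with median scaling, 170 without Rn45s and Mir6236, and 46 with only the compared groups in the fit, which has 4 residual degrees of freedom. The knockout in oxLDL had 2 genes with only its groups in the fit and 180 without the close pair. OxLDL in WT had 2593 with median scaling, 2641 with quantile normalization and 2080 without the close pair. The difference of responses, 1 gene, became 0 with a pseudocount of 0.1, 2 with a pseudocount of 5, and 0 at a TPM minimum of 5, with the length and GC trend removed and without the close pair. The averaged knockout had 517 genes without a filter. With an estimated correlation the called lists were 0 for each knockout contrast, 3 for oxLDL in each genotype and 0 for the difference. Fry called 0 for the knockout contrasts and the difference, but 14 for oxLDL in WT and 10 in Pim1-/- cells. The cholesterol synthesis list passed fry as a fall in both genotypes (fry adjusted p = 0.000262 and 0.00137). Fry does not set a list against the other genes, so the shift of the libraries can enter it. A pseudocount of 5 left 2 lists in the difference. Pim1 in PBS was -1.59 with median scaling, and the correlation of the responses was 0.765 and 0.868 with pseudocounts of 0.1 and 5. The cause was not tested for these changes, and apart from the fits and libraries below all other alternatives kept each count within 1.5 times.

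Leaving out each library gave 2 (without WT PBS 2) to 1669 (without Pim1-/- PBS 2) genes for the knockout in PBS, 1 to 317 (without WT oxLDL 2) in oxLDL, 2591 (without WT oxLDL 2) to 5114 (without WT PBS 3) for oxLDL in WT, 688 (without Pim1-/- oxLDL 3) to 2307 (without WT PBS 3) in Pim1-/- cells, 0 to 3 (without WT PBS 3) for the difference and 310 (without Pim1-/- oxLDL 2) to 2693 (without Pim1-/- PBS 2) averaged. Lists numbered 2 (without WT PBS 2) to 5 for the knockout in PBS, 4 to 5 in oxLDL, 10 to 14 for oxLDL in WT, 10 to 13 in Pim1-/- cells, and 1 (without WT PBS 1 or WT oxLDL 3) to 6 for the difference. Leaving out single libraries, the lists that lost their call did so in 3 of 12 fits (ATF4) and 1 of 12 (class II) for the knockout in PBS, 1 (adhesion) in oxLDL, 7 (mitotic), 4 (ATF4) and 1 (neutrophil) for oxLDL in WT, 6 (PPAR) in Pim1-/- cells, and 8 (ATF4), 7 (NRF2) and 2 (mesothelial) for the difference. The correlation of the responses ran from 0.775 (without Pim1-/- PBS 2) to 0.857. The other libraries that moved a count by over 1.5 times are given with each comparison above.

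Whether the replicate numbers pair the libraries is not known. Same-numbered libraries deviated from their group means with correlations of -0.52 to 0.17. Those between the oxLDL groups were all positive (0.067 to 0.17). Between treatments all were negative, from -0.18 to -0.034 in WT and from -0.29 to -0.11 in Pim1-/- cells. Libraries with different numbers were not compared in this way, so these values cannot settle it. A replicate block gave 321 genes for the knockout in PBS, 877 averaged, 0 for the difference and 2 lists in the difference, and a replicate block within genotype gave 817 for oxLDL in Pim1-/- cells and 0 for the difference. Depth is unknown, so what depth limits cannot be stated.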

Other observations

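The gene groups of the first 2 paragraphs belong to lists fixed beforehand, and of the tests that follow, those on library composition, length and GC content, differences between libraries, the close pair of libraries, sterol and endotoxin were chosen after the results had been seen, while the counts of other splits were planned. Lysosome and autophagy genes fell in 10 of 29 cases with oxLDL in WT cells and in 4 in Pim1-/- cells, and none rose, but median scaling gave 3 rises and 5 falls in WT and 2 falls in Pim1-/- cells (camera adjusted p = 0.109 and 0.102). Npc1, which exports cholesterol from lysosomes, changed by -3.07 and -1.99. Of 16 tested genes that mark large peritoneal macrophages 3 rose and 5 fell in WT (adjusted p = 0.54), with the coagulation factor gene F10 at 3.65 and Itga6 at -3.51, and 2 rose and 3 fell in Pim1-/- cells (adjusted p = 0.808).

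Genes of alternative activation moved both ways in WT cells (2 rose and 4 fell of 14, adjusted p = 0.281), with Ccl22 at 2.97 and Il10 at 2.33 against Cdh1 at -1.90 and Egr2 at -1.85, and with median scaling 4 rose and 1 fell. NRF2 targets likewise had 4 rises, among them the cystine transporter gene Slc7a11 (3.00), and 6 falls, among them Gclc (-2.99), which became 8 rises and 1 fall with median scaling (adjusted p = 0.161). Endoplasmic reticulum chaperones fell in 5 of 18 cases, Edem1 by -1.73, and with median scaling 1 rose and none fell (adjusted p = 0.53). The falls of the knockout in PBS overlapped those of oxLDL in WT, 2 comparisons that share the WT PBS libraries. Of 511 falls 393 (76.9%) were shared against 138 for independent lists, and of 77 rises 30 against 4.49. Across genes the changes correlated at r = 0.558, against 0.502 in 100 simulations of unchanged groups that shared simulated controls. The covariance was 0.724, against 0.172 in the simulations. Each simulated gene had independent noise, without differences shared across a library, so the gap in covariance does not measure an excess beyond the shared controls. The 3 shared controls are too few to leave 2 for each comparison, so part or all of the excess overlap may come from them. Leaving out WT PBS 2 alone took the count of 588 to 2.

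The 511 falls and 77 rises of the knockout in PBS may be biological or may follow differences between libraries. Library composition is argued against as the whole cause of the rises, since it shifts all genes alike. The other tested genes had a median change of -0.415 (upper quartile 0.249), so their typical shift ran the opposite way to the rises. The rises were picked for large changes in this same comparison. Their median of 2.42 (median SE 0.568) therefore lies above the other genes by selection and adds no evidence. Even so, only 2 of 77 rises stayed called with median scaling (median change 2.65, SE 0.601). There the median adjusted p went from 0.0376 to 0.0663, and fewer genes had an unadjusted p under 0.05 (3546 to 2878). A length and GC trend stays open for the rises. Without it 58 of 77 stayed called (median 2.53, SE 0.578), but its removal also took off the shift of each library, which raises the knockout changes. For the falls composition cannot be told apart from the knockout. With median scaling their median went from -2.01 to -1.43, the median SE from 0.453 to 0.415 and the median adjusted p from 0.0325 to 0.0917. The smaller change and the fewer small p among all genes were not separated. A length and GC trend stays open for the falls too, as 252 of 511 stayed called without it (median -1.58, SE 0.398, median adjusted p 0.0508). Here as well the removal took off the shift of each library, so the 2 were not separated. A difference between libraries that does not follow genotype stays open, since 74.4% of the falls were lower in both WT oxLDL 2 and WT oxLDL 3 than in WT oxLDL 1, against 25.1% of other genes, although the extent of the oxLDL response could also order these libraries. Only 1 of the 10 splits of the 6 libraries, the real one, reached 588 calls (highest other 5), but 10 splits are too few for a share under 0.05.

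The closeness of WT oxLDL 2 and Pim1-/- oxLDL 1 (rho = 0.977) was weighed against labels and a trend. The 2 libraries were also alike in Rn45s (20.9% and 21.5%), ribosomal protein share (3.08% and 3.19%) and median ratio to the mean library (0.806 and 0.772). Pim1-/- oxLDL 1 had the highest Pim1 level of the knockout libraries. Whether the 2 shared material or processing was not tested. Swapped labels are argued against, because Pim1-/- oxLDL 1 correlated at 0.94 or more with the other libraries of its own group and at most at 0.893 with the other WT oxLDL libraries. A length and GC trend is argued against too, as the correlation was 0.976 without it. A single wrong genotype label of WT oxLDL 2 cannot be told apart, because its Pim1 level of 56.0 TPM lies between the highest knockout library (47.8) and the lowest other WT library (68.5). Its correlations go with such a label. WT oxLDL 2 stood at 0.94 and 0.947 with the other Pim1-/- oxLDL libraries and at 0.884 and 0.899 with the other WT oxLDL libraries. The knockout in oxLDL had 1 called gene, with 3 of 10 splits as high (highest other 1) and 1367 genes at an unadjusted p under 0.05, and 317 called genes without WT oxLDL 2.

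The oxLDL response may reflect sterol brought by the lipoprotein, endotoxin in the preparation or oxidized lipid, and the groups hold neither native lipoprotein nor endotoxin alone. Sterol delivery would lower SREBP2 targets, which were called in WT (adjusted p = 1.9e-05, but adjusted p = 0.253 with an estimated correlation), and raise LXR targets, which were not (adjusted p = 0.841), so it stays open. Endotoxin stays open as well, since 60 of the 62 members of the NF-kB and interferon lists rose in both genotypes, as oxidized lipid might also bring about. In each genotype 1 of 10 splits, the real one, reached the observed 4137 and 1542 calls (highest other 9 and 2), and 10 splits are too few for a share under 0.05. For the averaged knockout 1 of 100 splits of the genotype labels within treatment, the real one, reached 1404 calls. This argues against a chance assignment of the labels to these libraries as the source of that count. The highest other split (967) exchanged WT oxLDL 2 and Pim1-/- oxLDL 1. Since the libraries of a group may not be separate animals or cultures, a difference between the sets of cells apart from genotype is not excluded.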
